A study of Rattus norvegicus with 12 samples.

How the data were processed

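RNA sequencing was done on cells labelled as primary nucleus pulposus (NP) cells of Wistar rats, the cells of the gel-like core of the intervertebral disc. Per the labels' protocols, cells grew out of explanted tissue in DMEM with serum and were transduced with lentivirus carrying a control shRNA vector (PLKO) or an shRNA against TonEBP (shTon). TonEBP, encoded by Nfat5, is the transcription factor that cells use to adapt to high osmolarity. Cells then received 50 ng/mL of the cytokine TNF-a for 24 h or were left untreated, and RNA was extracted with Qiagen RNeasy columns and treated with DNase, per the labels' protocols. The 12 libraries form 4 groups of 3, named PLKO_CTR, PLKO_TNF, shTon_CTR and shTon_TNF after the sample titles, which also number the libraries of each group as sets 1, 2 and 3. The labels do not say whether a set is an animal, a culture or a day, so p-values measure only the spread between these samples. Among sets 5594 of 12310 genes (45.4%) differed at an adjusted p under 0.05 in limma. Skeletal muscle markers had median log2 deviations of 3.21, 1.46 and -4.46 in sets 1 to 3. This argues against sets as technical repeats of 1 culture. Whether they are separate animals is not known. Library kit, strandedness and read length are not given in the sources used here.

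The authors deposited 3 tables, each of 6 libraries in 2 groups: PLKO_CTR with PLKO_TNF (13373 genes), PLKO_CTR with shTon_CTR (13305 genes) and PLKO_TNF with shTon_TNF (13176 genes). Per the submitters' processing notes, Novoalign 2.08.01, DESeq2 (version not given) and the rat genome build rn5 were used, with no role or order stated. The deposited per-library values are a normalised signal per gene, per the file headers. They are gene read counts divided by 1 factor per library, as their steps show: every value was a whole multiple of the smallest value above 0 of its library, within 0.001 read, for 100% of the values in each table. Each table was scaled by itself. The deposited log2 fold changes and adjusted p-values are the authors' own, and their model is not given in the sources used here. DESeq2 with a fold-change prior and the set as a term came close to them: the median absolute difference in log2 fold change was 0.000452, 0.000416 and 0.000607 in the 3 tables, and 1341, 392 and 357 genes passed where the authors' deposited tables hold 1339, 406 and 371. Without the set term that refit gave 141, 19 and 38 genes. A fold-change prior draws uncertain fold changes toward 0, and limma's estimates have none. Deposited fold changes set beside limma's below are therefore not the same measure. An adjusted p was listed as NA for 15.0% of genes in each of the authors' deposited tables and was kept as NA.

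The read counter, the annotation release, the gene filter and the handling of reads that map to several places are not given in the sources used here. Values of genes with near-identical relatives (Cxcl1, Cxcl2 and Cxcl3, Ccl3, Ftl1, Akr1b1 and Akr1b8, Mt1) are uncertain for that reason, and overlapping or antisense genes could not be told apart. Genes carry Ensembl rat identifiers and symbols in the tables, and 18, 18 and 17 names had been turned into dates. No annotation of the authors' build was used here, so no coordinates are given.

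Reads per library were recovered by dividing out the step. The libraries held 7160042 to 18646798 reads on listed genes, at least 9114089 in the PLKO groups and at most 12511943 in the shTon groups. Libraries that stand in 2 tables had equal reads in 100% of the 13190 or 13082 genes that both list, so the tables could be joined over the 12899 genes common to the 3, with DESeq2 size factors over the 12 libraries. Within a group, chi-square per degree of freedom between libraries was 73.3 to 167, so no library was a copy of another of its group, and copies across groups were not tested. Every per-sample column had a sample.

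The design fixed before the data were examined named an edgeR quasi-likelihood test for raw counts and limma on log2(value + 1) for normalised values. The tables hold normalised values, so limma is the main test. Each comparison used its 2 groups alone, without the set in the model, on genes with a mean of at least 10 normalised reads, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. That filter and the trend were not part of the fixed design. The 3 deposited pairs were fitted on the deposited values. The effect of TNF-a within shTon cells and the interaction (the difference between the effects of TNF-a in shTon and PLKO cells, all 12 libraries) were fitted on the jointly scaled recovered reads. Log2 fold changes are on the log2(value + 1) scale, which understates changes of low genes, and SE is the moderated standard error of limma.

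Whether set numbers pair the libraries was checked before the fits were compared. Deviations from group means correlated at 0.674 to 0.886 in the 12 pairs of libraries with the same set number and at -0.739 to 0.179 in the 24 other pairs. Every same-set pair exceeded 0.1, so the set pairs the libraries, and each result is given with the set as a block as well. Unless another source is named, SE and adjusted p in the text are from limma with the set as a block, and "rose" and "fell" are used of genes that passed that test. Means are of normalised reads in the scale of the comparison's own table, ± SD with n = 3 libraries per group.

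Other settings were a pseudocount of 0.1, no filter, adjusted p under 0.01, a fold of at least 2, no trend, TMM scaling, all 12 libraries in 1 fit, each set left out, and count tests on the recovered reads (edgeR quasi-likelihood with TMM or RLE scaling and 3 read filters, and DESeq2). The combinations of the block with another setting, the edgeR runs, TMM scaling, the fits without a trend, and a fit without the set 1 library labelled shTon_TNF were added after the data were seen. Scaling by TMM moved the median of all genes by at most 0.00923 on the log2 scale. With a set left out and the block in the model, very few residual degrees of freedom remain. P-values and counts of such fits are not directly comparable with those of all sets.

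Gene groups were 24 lists with 482 entries, fixed before the data were examined, of which 405 distinct genes had a value. A list with 5 or more tested members was tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Fits of 6 libraries leave few degrees of freedom, above all with the block, so the estimated correlation is imprecise. A list that did not pass with it is therefore not shown to be unmoved. Counts of members that passed are given over all genes tested and adjusted over the list alone. Genes named in the text were to be Nfat5, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap and whose mean was at least 1 CPM, and up to 4 members of each list that passed, or the member with the smallest p where none did. The test without the block passed 0 genes in 4 of the 5 comparisons and 6 for TNF-a in shTon cells. The rule was applied to the test with the block in all 5, a choice made after the data were seen. Other genes are said to be such where they are named. The text names fewer genes than the rule allows, and the values of some that it covers are not reported here.

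The fits were tested on simulated data with 100 genes changed by a fold of 2 and 100 by a fold of 4. With the set as a block, limma recovered 82 and 97 of these for TNF-a in PLKO cells (12367 genes run, 11 false calls), 71 and 92 for knockdown without TNF-a (12356 genes, 8 false), 58 and 96 for knockdown with TNF-a (12211 genes, 13 false), 76 and 97 for TNF-a in shTon cells (12307 genes, 14 false) and 18 and 76 for the interaction (12291 genes, 5 false). Without the block it recovered 2 and 43, 0 and 32, 0 and 37, 3 and 45, and 1 and 35 in the same order, with 0 false calls. The software was R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.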

Results

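Gene expression was measured in 12 RNA-seq libraries of rat NP cells that carried a control shRNA vector (PLKO) or an shRNA against TonEBP (shTon) and were left untreated (CTR) or given 50 ng/mL TNF-a for 24 h (TNF). Each of the 4 groups held 3 libraries, numbered as sets 1 to 3, with 7160042 to 18646798 reads on listed genes. TNF-a is an inflammatory cytokine found in degenerating discs, and the series asks how TonEBP bears on the response of disc cells to it. The libraries separated first by set. The first principal component held 55.4% of the variance, and 5594 of 12310 genes (45.4%) differed among sets at an adjusted p under 0.05 in limma. Skeletal muscle markers were among these, with 10 of 10 tested genes differing. Acta1, skeletal muscle actin, averaged 21370.0 ± 6634 normalised reads in set 1, 5746 ± 1918 in set 2 and 34.0 ± 31.4 in set 3 (SD, n = 4 libraries per set, 1 of each group). The cultures of sets 1 and 2 thus held muscle transcripts at high levels. Cell types within a culture could not be told apart, so the effects below are of whole cultures and not of NP cells alone.

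Nfat5, the gene that the shRNA targets (ENSRNOG00000011879), was lower with knockdown in untreated cells. Its level was 1289 ± 570.3 normalised reads in PLKO_CTR and 401 ± 98.0 in shTon_CTR (SD, n = 3, joint scale). It was lower in 3 of 3 sets (log2 ratios -0.59, -1.58 and -2.66, in the scale of the deposited table, as are the ratios below). With TNF-a the levels were 739 ± 316 in PLKO_TNF and 809 ± 779 in the libraries labelled shTon_TNF. In sets 2 and 3 the library labelled shTon_TNF was lower than its control (log2 ratios -1.12 and -1.06). In set 1 it held 1695 normalised reads against 642 (1.41), so Nfat5 goes against the label of that library. None of the fold changes of Nfat5 in the 3 deposited pairs passed the test with the set as a block and all 3 sets. They were -1.61 for knockdown without TNF-a (SE 0.33, adjusted p = 0.0963), -0.26 with TNF-a (SE 0.44, adjusted p = 0.799) and -0.78 for TNF-a in PLKO cells (SE 0.32, adjusted p = 0.165). The authors' deposited tables list -1.19 (adjusted p = 4.57e-05), -0.03 (0.987) and -0.45 (0.43) for the same comparisons. With the block, the value for knockdown with TNF-a was -1.09 without set 1 (adjusted p = 0.00941), 0.18 without set 2 (adjusted p = 0.954) and 0.15 without set 3 (adjusted p = 0.898). The value without set 1 rests on sets 2 and 3 alone, after the discordant set was removed. Its adjusted p is therefore not comparable with that of the test on all 3 sets. Every direction of knockdown with TNF-a below rests on the libraries as labelled.

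**Figure D1:**
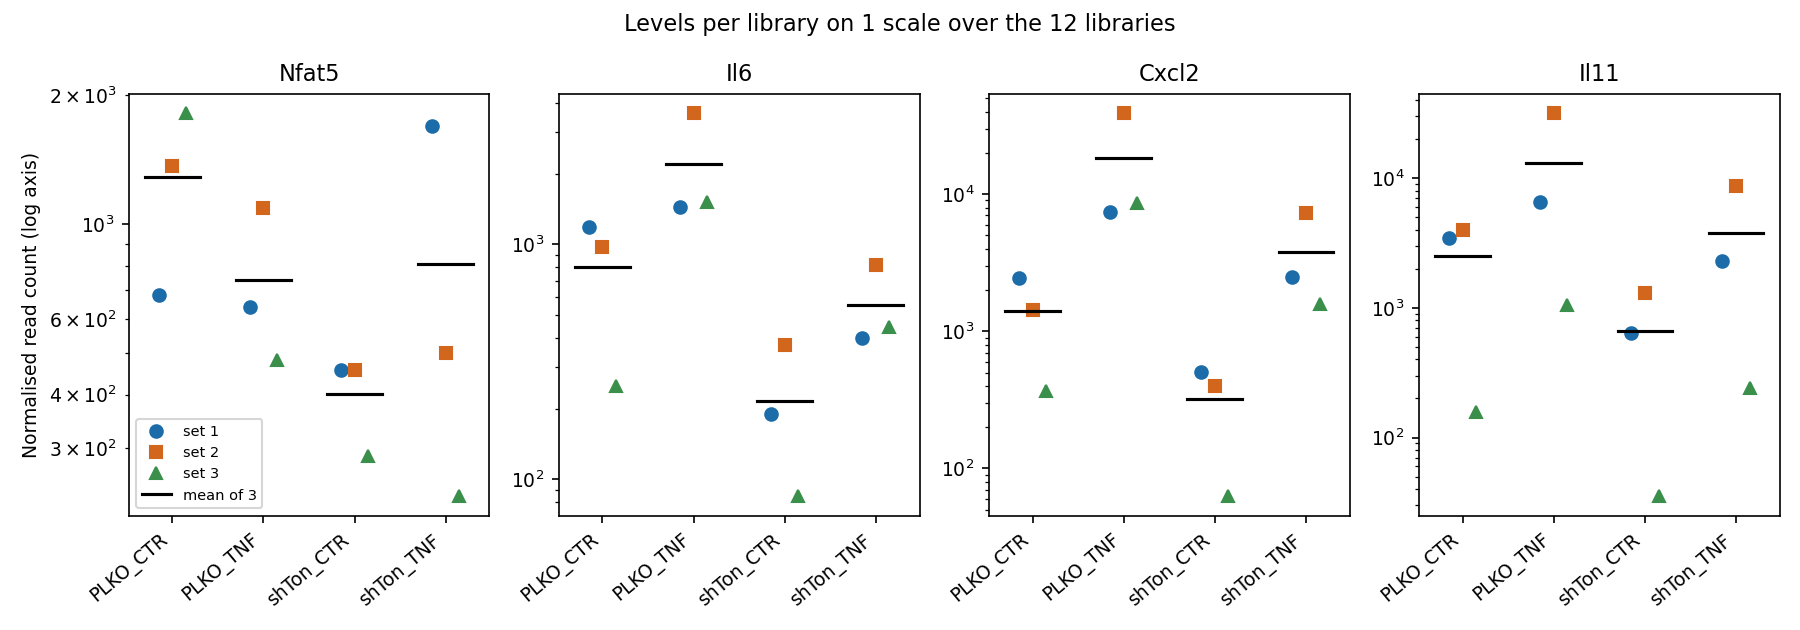
Normalised reads of Nfat5, Il6, Cxcl2 and Il11 in each library on a log axis, by group, with 1 symbol per set (circle, set 1; square, set 2; triangle, set 3) and a line at the mean of the 3 libraries. Nfat5 stands at 1695 in the set 1 library labelled shTon_TNF, while Il6, Cxcl2 and Il11 are lower in the shTon than in the PLKO library of the same set, with and without TNF-a.

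TNF-a changed inflammatory and matrix genes in cells with the control vector (PLKO_TNF against PLKO_CTR). Mmp9, a gelatinase, rose from 184 ± 59.5 to 2728 ± 1418 normalised reads (log2 fold change 3.79, SE 0.21, adjusted p = 0.000685). Ccl20, a chemokine that draws lymphocytes, rose from 1315 ± 1022 to 12516 ± 6898 (3.49, SE 0.21, adjusted p = 0.000886). The largest rises by limma's estimate among the named genes were of Mmp12, macrophage elastase (5.01, SE 0.45, adjusted p = 0.00351), and of the interleukin genes Il1b (4.96, SE 0.37, adjusted p = 0.00176) and Il23a (4.78, SE 0.44, adjusted p = 0.00351). Ibsp, a bone matrix sialoprotein gene, followed (4.17, SE 0.39, adjusted p = 0.00351). The authors' deposited table ranks these genes lower, with 1.69, 1.59, 1.71 and 1.88, against 3.38 for Mmp9 and 3.10 for Ccl20. Its values came close to a fit with a fold-change prior, which draws uncertain values toward 0, so they are not the same measure as limma's. Gas1, a growth-arrest gene, fell from 375 ± 94.6 to 38.4 ± 6.12 (-3.23, SE 0.24, adjusted p = 0.00176). Cdo1, cysteine dioxygenase, fell from 2065 ± 1774 to 261 ± 127 (-2.68, SE 0.39, adjusted p = 0.0133). In all, 1190 of 12373 genes passed limma with the set as a block, 615 higher and 575 lower with TNF-a, and the authors' deposited table lists 1339 (677 and 662). Without the block limma passed 0 genes (smallest adjusted p 0.0686, 793 genes at an unadjusted p under 0.05), edgeR 0 (787) and DESeq2 146. The blocked count was 545 without set 2, 696 with all 12 libraries in the fit and 55 without the mean-variance trend, which the fixed design did not name.

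Of the inflammatory lists, 4 passed camera with the preset correlation for TNF-a in PLKO cells and 0 with an estimated one. Of 20 tested genes of TNF/NF-kB feedback and adhesion, 14 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 1.25. The feedback inhibitor gene Tnfaip3 went from 438 ± 86.7 to 3012 ± 591 normalised reads (2.78, SE 0.11, adjusted p = 0.000213). The NF-kB subunit gene Nfkb2 had 2.04 (SE 0.10, adjusted p = 0.000531). Of 16 chemokines 8 rose and 1 fell (9 and 1 over the list alone, median 1.36). Cxcl2 (3.65, SE 0.56, adjusted p = 0.0158) and Cxcl3 (2.70, SE 0.30, adjusted p = 0.00632), which attract neutrophils, were among the rises. The chemokine that fell was Cxcl12 (-1.16, SE 0.19, adjusted p = 0.0177, but 0.269 with all 12 libraries in the blocked fit), named after its value was seen. Of 15 cytokines and colony-stimulating factors 9 rose and 0 fell (9 and 0 over the list alone, median 1.59), as Il1a did (3.59, SE 0.25, adjusted p = 0.00132). Il6, also named after its value was seen, had 1.59 (SE 0.38, adjusted p = 0.0471, but 0.0799 without set 2). The authors' deposited table lists 0.73 for Il6 with adjusted p = 0.129. Of 12 inflammatory mediator enzymes 7 rose and 0 fell (7 and 1 over the list alone, median 0.61). They include Ass1, argininosuccinate synthase (3.15, SE 0.13, adjusted p = 0.000213), the prostaglandin synthase gene Ptgs2 (2.28, SE 0.40, adjusted p = 0.0212) and the nitric oxide synthase gene Nos2 (1.63, SE 0.18, adjusted p = 0.00590). Camera with the preset correlation gave these 4 lists adjusted p of 1.42e-12, 1.04e-06, 1.23e-05 and 0.000880. Each of them had adjusted p = 0.445 with an estimated correlation, which so few libraries estimate poorly.

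Matrix genes moved both ways with TNF-a. Of 24 tested matrix metalloproteinases, ADAMTS proteases and inhibitors, 7 rose and 4 fell (8 and 8 over the list alone). The stromelysin gene Mmp3 rose from 27885 ± 14761 to 180169 ± 60648 normalised reads (log2 fold change 2.75, SE 0.28, adjusted p = 0.00455), and Mmp10 had 2.99 (SE 0.30, adjusted p = 0.00455). The 4 that fell, named after their values were seen, were Adamts15 (-1.27), Adamts2 (-0.75), Mmp19 (-0.67) and the inhibitor gene Timp2 (-0.47). Adamts15 lost its call without set 2 (adjusted p = 0.0696) or 3 (0.0542), Adamts2 without set 2 (0.147), Mmp19 without set 1 (0.0533) or 3 (0.0503), and Timp2 with any 1 set left out (0.0576, 0.134 and 0.212). The list as a whole did not pass (median -0.02, mean 0.57, adjusted p = 0.328 with direction up). Of 28 fibrillar matrix and fibroblast genes 0 rose and 6 fell (1 and 10 over the list alone, median -0.34). This list had adjusted p = 0.00134, and adjusted p = 0.673 with an estimated correlation. Col3a1, a fibrillar collagen gene, had -1.70 (SE 0.22, adjusted p = 0.00934) and Col6a3 -1.31 (SE 0.24, adjusted p = 0.0239, but 0.185 with all 12 libraries in the blocked fit). Col3a1 also differs among sets, with means of 20758 ± 11700.3, 22952 ± 13308 and 1594 ± 1126 normalised reads in sets 1 to 3 (n = 4).

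Among disc phenotype genes, 2 of 10 nucleus pulposus and notochord markers rose and 3 fell (2 and 6 over the list alone, adjusted p = 0.180). Ibsp, a bone matrix gene that the fixed lists count among the nucleus pulposus markers, rose as given above. The transcription factor gene Pax1 fell (-1.45, SE 0.26, adjusted p = 0.0232), as did the keratin gene Krt8 (-1.10, SE 0.20, adjusted p = 0.0230) and the galectin gene Lgals3 (-0.97, SE 0.13, adjusted p = 0.0110). Of 20 cartilage and nucleus pulposus matrix genes 2 rose and 1 fell (2 and 4 over the list alone, adjusted p = 0.344). The hyaluronan synthase gene Has2 rose (1.60, SE 0.28, adjusted p = 0.0218, but 0.106 with all 12 libraries in the blocked fit) and the link protein gene Hapln1 fell (-1.63, SE 0.18, adjusted p = 0.00682). Of 5 annulus fibrosus and tendon markers 0 rose and 2 fell (0 and 3 over the list alone, median -0.76), among them Scx, a tendon transcription factor gene (-0.76, SE 0.12, adjusted p = 0.0157). That list had adjusted p = 0.0344, against 0.0679 without the block, 0.0742 without set 1 and adjusted p = 0.445 with an estimated correlation. Skeletal muscle markers, which differ among sets, had a median of -0.45 (adjusted p = 0.0623), and 1 of 10 fell, Myod1 (-1.49, SE 0.20, adjusted p = 0.0112). Of 13 osmoprotective targets of TonEBP, 1 rose and 1 fell (3 and 2 over the list alone, adjusted p = 0.677). These were the hexose transporter gene Slc2a6 (1.23, SE 0.26, adjusted p = 0.0357, but 0.0953 without set 3) and the small heat-shock protein gene Hspb1 (-0.66, SE 0.10, adjusted p = 0.0132).

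The remaining lists were tested for TNF-a in PLKO cells as well. The unfolded protein and integrated stress response list had 3 of 23 members higher and 1 lower (5 and 1 over the list alone, median 0.25). Creld2, an endoplasmic reticulum chaperone gene, had 0.91 (SE 0.17, adjusted p = 0.0245). The list had adjusted p = 0.0182, against 0.206 without the block, 0.0742 without set 1 and adjusted p = 0.445 with an estimated correlation. Antigen presentation had 2 of 17 members higher and 0 lower (3 and 0 over the list alone, median 0.27), among them the peptide-loading gene Tapbp (0.73, SE 0.13, adjusted p = 0.0212). Its adjusted p was 0.0202, against 0.206 without the block, 0.0827 without set 1, 0.192 without set 3 and adjusted p = 0.673 with an estimated correlation. Interferon-response genes had 3 higher and 1 lower of 23 (3 and 2 over the list alone, adjusted p = 0.760). Irf1 (1.31, SE 0.15, adjusted p = 0.00766) and the GTPase gene Gbp5 (1.58, SE 0.20, adjusted p = 0.00915) were among those that rose. The p53 and apoptosis list had 4 of 24 higher and 1 lower (4 and 2 over the list alone, adjusted p = 0.328), led by the survival gene Bcl2a1 (3.05, SE 0.28, adjusted p = 0.00351). Cytokine and pattern-recognition receptors had 2 higher and 1 lower of 21 (3 and 4 over the list alone, adjusted p = 0.564). Cell cycle genes had 0 and 3 of 36 (0 and 4, 0.328), and glycolysis and hypoxia genes 2 and 1 of 27 (2 and 1, 0.619). Sterol synthesis (21 genes, 0.135), bone and osteoclast markers (6 genes, 0.180) and mitochondrially encoded genes (9 genes, 0.285) had 0 members past the threshold. The bone list does not hold the bone matrix gene Ibsp, which rose and is counted with the nucleus pulposus markers.

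Knockdown without TNF-a (shTon_CTR against PLKO_CTR), which asks what the TonEBP shRNA does in unstimulated cells, gave the changes that follow. Cxcl2 fell from 1485 ± 1089 to 338 ± 242 normalised reads (log2 fold change -2.22, SE 0.16, adjusted p = 0.0197). Il11, a cytokine gene of the IL-6 family, fell from 2662 ± 2179 to 688 ± 659.8 (-2.06, SE 0.17, adjusted p = 0.0259). Csf3, the granulocyte colony-stimulating factor gene, had -1.66 (SE 0.18, adjusted p = 0.0394). Il1rn, the interleukin-1 receptor antagonist gene, fell from 427 ± 98.0 to 174 ± 26.5 (-1.27, SE 0.15, adjusted p = 0.0438). Sacm1l, a phosphoinositide phosphatase gene, had -1.17 (SE 0.13, adjusted p = 0.0394). Without set 2 these last 2 had adjusted p of 0.155 and 0.127. Of genes named after their values were seen, the stanniocalcin gene Stc1 (-1.85, SE 0.19, adjusted p = 0.0394) and the ferritin light chain gene Ftl1 (-1.21, SE 0.11, adjusted p = 0.0394) fell. Pappa, a protease of IGF-binding proteins, rose from 2819 ± 2168 to 6015 ± 4466 (1.22, SE 0.14, adjusted p = 0.0394). Aldh1l2, a mitochondrial folate enzyme gene, had 1.44 (SE 0.16, adjusted p = 0.0394). Without set 2, Ftl1, Pappa and Aldh1l2 had adjusted p of 0.0834, 0.0648 and 0.0611. With all 12 libraries in the blocked fit Sacm1l and Ftl1 passed. Cxcl2 (0.103), Csf3 (0.218) and Il1rn (0.248) did not, nor did Il11, Stc1, Pappa and Aldh1l2 (0.0585 each). Il6 had -1.86 (adjusted p = 0.0559), where the authors' deposited table lists -1.49 with adjusted p = 1.77e-09.

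With the block, 14 of 12383 genes passed for knockdown without TNF-a, 2 higher and 12 lower, and the authors' deposited table lists 406 (141 and 265). Without the block limma and edgeR passed 0 genes (504 of 12383 and 494 of 12225 at an unadjusted p under 0.05), and DESeq2 20. The blocked count was 0 without the mean-variance trend, 2 with a pseudocount of 0.1 and 3 with all 12 libraries in the fit. It was 17 in edgeR, 399 in DESeq2, 283 without set 1 and 220 without set 3. Of 16 chemokines 0 rose and 1 fell, and 15 were lower by value (0 and 11 over the list alone, median -1.09, adjusted p = 1.06e-09). Of 12 cytokines 0 rose and 3 fell (0 and 6 over the list alone, median -0.85, adjusted p = 8.67e-06). Of 13 mediator enzymes 0 passed (1 and 6 over the list alone, median -0.43, adjusted p = 0.00886, but 0.0599 without set 1). These 3 lists had adjusted p = 0.456 with an estimated correlation. The TNF/NF-kB feedback list did not pass (0 of 20, median -0.17, adjusted p = 0.0969). Neither did the osmoprotective targets (0 of 13, 2 higher and 3 lower over the list alone, median -0.01, adjusted p = 0.576). In that list the kinase gene Sgk1 had -0.77 (SE 0.16, adjusted p = 0.0933), where the authors' deposited table lists -0.65 with adjusted p = 0.0141. The taurine transporter gene Slc6a6, named after its value was seen, had -0.50 (SE 0.13, adjusted p = 0.133, and 0.106 in the authors' deposited table).

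The cell cycle and sterol synthesis lists passed camera with the preset correlation for knockdown without TNF-a, but not with an estimated one. Of 36 cell cycle genes 35 were lower by value and 0 passed (0 and 0 over the list alone, median -0.34, adjusted p = 8.67e-06). Cdc6, a replication licensing gene, had -0.74 (SE 0.19, adjusted p = 0.135). Of 21 sterol synthesis genes 18 were lower by value and 0 passed (median -0.28, adjusted p = 0.00102, but 0.396 without set 2), for example Msmo1 (-0.55, SE 0.13, adjusted p = 0.119). Both lists had adjusted p = 0.596 with an estimated correlation. The p53 and apoptosis list was higher (4 and 0 of 24 over the list alone, median 0.21, adjusted p = 0.0115, and adjusted p = 0.456 with an estimated correlation). Sesn2, a stress-response gene, had 1.13 (SE 0.19, adjusted p = 0.0841). Fibrillar matrix genes had a median of 0.11 (8 and 0 of 28 over the list alone). Their adjusted p was 0.0321, against 0.153 without the block, 0.463 without set 1 and adjusted p = 0.596 with an estimated correlation. In the same comparison 8 of 10 skeletal muscle markers were higher by value (1 and 0 over the list alone, median 0.38). Their adjusted p was 0.0108, against 0.625 without the block, 0.259 without set 1 and adjusted p = 0.456 with an estimated correlation. Of 9 mitochondrially encoded genes 8 were higher by value (0 and 0 over the list alone, median 0.39). Their adjusted p was 0.0321, against 0.186 without the block, 0.544 without set 1, 0.131 without set 3 and adjusted p = 0.596 with an estimated correlation.

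Knockdown with TNF-a (libraries labelled shTon_TNF against PLKO_TNF), the comparison closest to the question of the series, gave the changes below. Il6 fell from 2095 ± 1191 to 528 ± 218 normalised reads (log2 fold change -1.92, SE 0.16, adjusted p = 0.0231). Cxcl2 fell from 17615 ± 17249.5 to 3608 ± 2917 (-2.15, SE 0.22, adjusted p = 0.0279) and Il11 from 12543 ± 15729 to 3587 ± 4227 (-1.83, SE 0.18, adjusted p = 0.0279). Other falls were of Ccl3, a macrophage chemokine gene (-2.51, SE 0.30, adjusted p = 0.0321), and Ereg, an EGF receptor ligand gene (-2.10, SE 0.23, adjusted p = 0.0279). Akr1b8, an aldo-keto reductase gene (-1.97, SE 0.23, adjusted p = 0.0314), and Nampt, an enzyme gene of NAD synthesis (-1.41, SE 0.17, adjusted p = 0.0314), fell too. Col3a1 rose from 4701 ± 3818 to 15476 ± 12752 (1.53, SE 0.21, adjusted p = 0.0389), and Col5a3, a minor fibrillar collagen gene, from 202 ± 76.9 to 747 ± 460.1 (1.75, SE 0.20, adjusted p = 0.0314). Adamts2, which trims procollagens, rose from 211 ± 18.9 to 597 ± 186 (1.45, SE 0.20, adjusted p = 0.0389). Sulf2, a heparan sulfatase gene, had 1.44 (SE 0.15, adjusted p = 0.0279). Wnt11, a Wnt ligand gene, had 2.58 (SE 0.33, adjusted p = 0.0389, but 0.0652 without set 3). In edgeR with the block Col3a1 did not pass (adjusted p = 0.0658). With all 12 libraries in the blocked fit Cxcl2 did not pass (0.0614). With the set 1 library labelled shTon_TNF left out of that fit, Il6 (0.0642), Cxcl2 (0.129), Il11 (0.0519), Ccl3 (0.0507) and Akr1b8 (0.0696) did not.

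With the block, 31 of 12213 genes passed for knockdown with TNF-a, 14 higher and 17 lower, and the authors' deposited table lists 371 (170 and 201). Without the block limma and edgeR passed 0 genes (770 of 12213 and 768 of 12190 at an unadjusted p under 0.05), and DESeq2 41. The blocked count was 0 without the mean-variance trend, 12 with a pseudocount of 0.1, 21 in edgeR, 367 in DESeq2, 488 without set 1 and 157 without set 2. It was 444 with all 12 libraries in the fit and 296 when the set 1 library labelled shTon_TNF was left out of that fit. Of 16 chemokines 0 rose and 2 fell (0 and 10 over the list alone, median -0.79, adjusted p = 1.47e-08). Of 15 cytokines 0 rose and 3 fell (0 and 6 over the list alone, median -0.82, adjusted p = 1.63e-05). Both lists had adjusted p = 0.390 with an estimated correlation. Of 13 mediator enzymes 0 passed (1 and 5 over the list alone, median -0.40). Their adjusted p was 0.0329, against 0.0600 without set 2 and adjusted p = 0.589 with an estimated correlation. The TNF/NF-kB feedback list did not pass (0 of 20, median -0.03, adjusted p = 0.755). The osmoprotective targets did not either (0 of 13, 2 higher and 3 lower over the list alone, median -0.09, adjusted p = 0.345). In that list Akr1b1, aldose reductase, which makes the osmolyte sorbitol, had -0.66 (SE 0.17, adjusted p = 0.135). The authors' deposited table lists -0.59 for Akr1b1 with adjusted p = 0.0336.

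Of the matrix lists, 2 of 3 passed camera with the preset correlation for knockdown under TNF-a, and 0 with an estimated one. Of 28 fibrillar matrix and fibroblast genes 1 rose, Col3a1 (not in edgeR), and 0 fell (7 and 0 over the list alone, median 0.44). Their adjusted p was 0.000362, against 0.0602 without set 1 and adjusted p = 0.589 with an estimated correlation. Of 20 cartilage and nucleus pulposus matrix genes 0 passed (5 and 0 over the list alone, median 0.65, adjusted p = 0.00102, and adjusted p = 0.559 with an estimated correlation). The metalloproteinase list had 2 higher and 0 lower of 24, Adamts2 and Adamts12 (6 and 6 over the list alone, adjusted p = 0.920). Adamts12 had 1.18 (SE 0.17, adjusted p = 0.0478, but 0.0773 without set 2 and 0.0517 in edgeR with the block). The cell cycle list was lower, with 33 of 35 genes lower by value and 0 past the threshold (median -0.47, adjusted p = 1.69e-07, and adjusted p = 0.589 with an estimated correlation). Sterol synthesis was lower by value in 17 of 21 genes (median -0.30, adjusted p = 0.0118, against 0.551 without set 2 and adjusted p = 0.656 with an estimated correlation). The p53 and apoptosis list was higher (4 and 1 of 24 over the list alone, median 0.27). Its adjusted p was 0.00847, against 0.0648 without set 3 and adjusted p = 0.589 with an estimated correlation. Antigen presentation had a median of 0.26 over 17 genes with adjusted p = 0.0486, against 0.111 without the block, 0.318 without set 2, 0.182 without set 3 and adjusted p = 0.589 with an estimated correlation. In the same comparison 8 of 9 mitochondrially encoded genes were higher by value (3 and 0 over the list alone, median 0.77). Their adjusted p was 0.00307, against 0.0602 without set 1 and adjusted p = 0.589 with an estimated correlation. Of 10 skeletal muscle markers 8 were higher by value (median 0.41, adjusted p = 0.211).

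**Figure D2:**
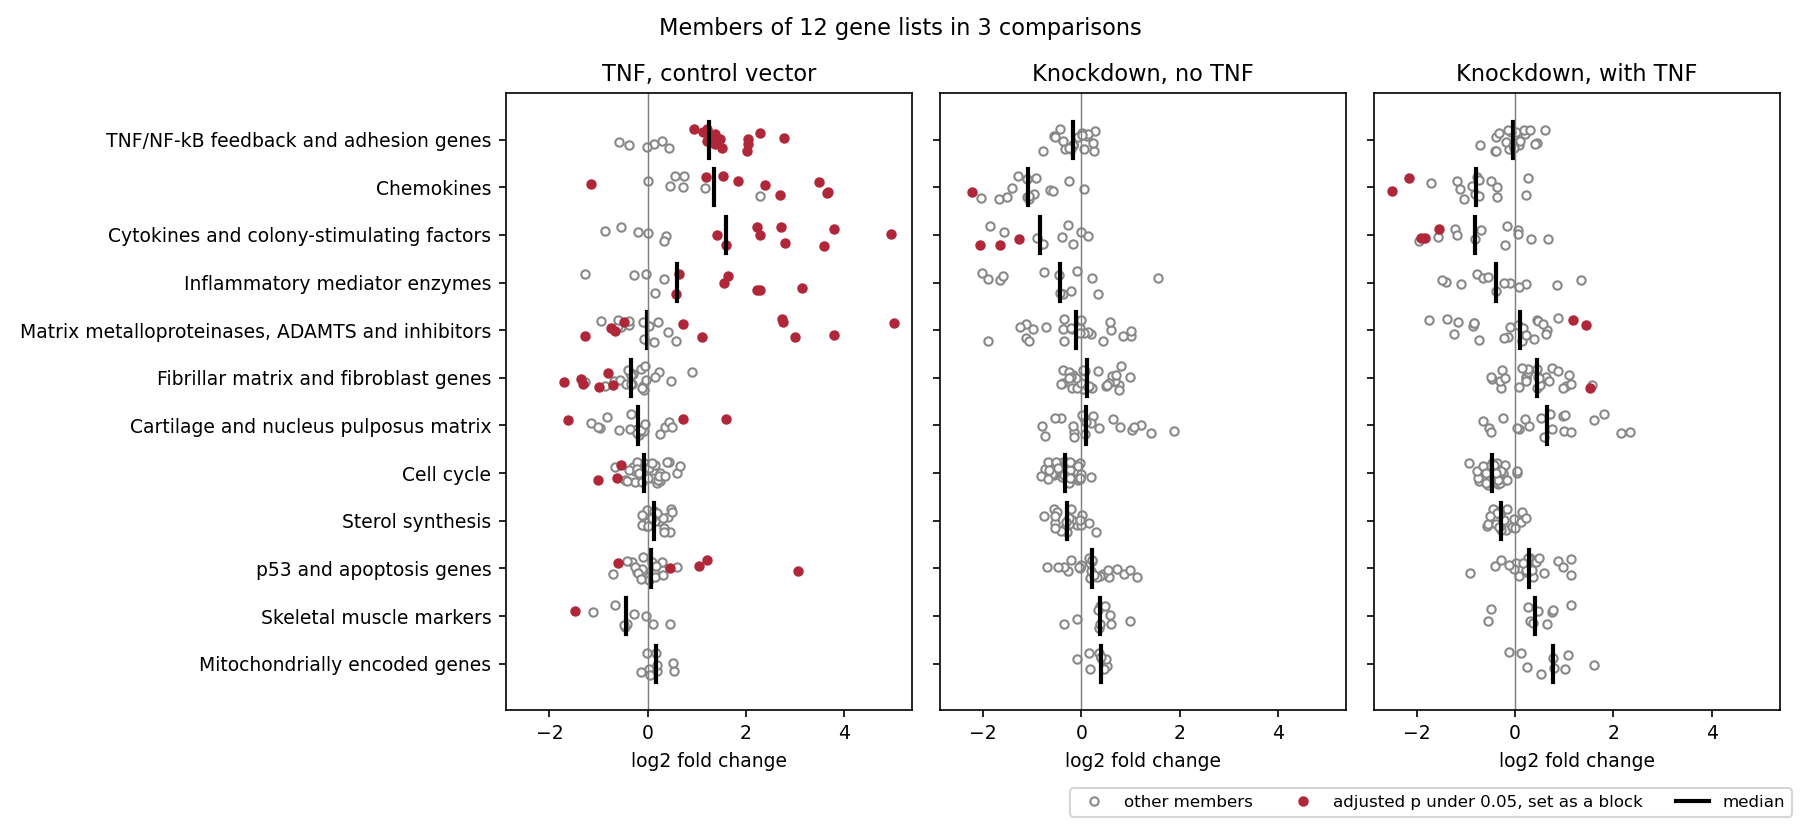
Log2 fold changes of the members of 12 gene lists (points, 1 per gene) for TNF-a in PLKO cells, knockdown without TNF-a and knockdown with TNF-a, with a black bar at the median of each list and genes with an adjusted p under 0.05 (limma, set as a block) in red. Chemokines and cytokines have medians above 0 with TNF-a (1.36 and 1.59) and below 0 with knockdown (-1.09 and -0.85 without TNF-a, -0.79 and -0.82 with it), while the TNF/NF-kB feedback genes have 1.25 with TNF-a and -0.17 and -0.03 with knockdown.

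Genes raised by TNF-a in PLKO cells were next set against knockdown under TNF-a. With the block, 11 of the 615 TNF-raised genes (1.79%) were among the 17 that knockdown lowered (64.7% of these), where independent lists would share 0.862 of 12133 genes. The 11 were Cxcl2, Akr1b8, Ccl3, Il11, Egln3, Il6, Ereg, Plet1, Csf3, Nampt and Slc7a11. For TNF-a in PLKO cells the authors' deposited table has Il6 (adjusted p = 0.129), Csf3 (0.108) and Akr1b8 (0.0884) above 0.05. Cxcl2, Ccl3, Il11, Egln3, Plet1 and Slc7a11 are under 0.05 in it. The cystine transporter gene Slc7a11, named after its values were seen, rose with TNF-a (2.15, SE 0.33, adjusted p = 0.0157) and was lower with knockdown (-1.58, SE 0.21, adjusted p = 0.0389, but 0.0595 without set 3 and 0.0634 in edgeR with the block). Of the 564 TNF-lowered genes, 6 were among the 14 that knockdown raised (0.651 for independent lists), namely P2ry6, Col3a1, Tmem26, Sulf2, Adamts2 and Pappa. Plau, urokinase, was the 1 gene that rose with both (0.710 for independent lists). Its values were 2.69 for TNF-a (SE 0.17, adjusted p = 0.000886) and 1.32 for knockdown (SE 0.18, adjusted p = 0.0389, but 0.0557 without set 3 and 0.0517 in edgeR with the block). No gene fell with both (0.790 for independent lists). The authors' deposited tables give 82 TNF-raised genes lower with knockdown (12.2 for independent lists) and 9 higher (9.94). They give 2 TNF-lowered genes lower with knockdown (11.6) and 32 higher (9.49). Without the block the first overlap was 0 in limma and edgeR and 3 in DESeq2. Of the 11 genes, Il6 (adjusted p = 0.0799), Csf3 (0.0510), Akr1b8 (0.0537) and Plet1 (0.0648) lost the call for TNF-a without set 2, and Csf3 (0.0557) and Egln3 (0.0507) that for knockdown without set 3, beside Slc7a11. Plet1 also lost the call for TNF-a without set 1 (0.0882). Csf3 lost that for knockdown with all 12 libraries in the blocked fit (0.164), and for Cxcl2 in that fit and Csf3 in edgeR with the block adjusted p was 0.0614 and 0.0527. With the block, that overlap was 9 in edgeR, 89 in DESeq2, 42 with all 12 libraries in the fit, 79 without set 1 and 27 without set 2.

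The PLKO_TNF libraries stand in both of these comparisons, so part of the overlap may come from their chance values. Simulated groups without any effect that share 3 libraries gave an overlap of 0 in 100 simulations, which the lack of any effect fixes and which says nothing about the shared libraries. Their fold changes correlated across genes at -0.50 (-0.53 to -0.47), against -0.34 observed over 12310 genes (Spearman's rho -0.35), and genes are not independent replicates. The covariance was -0.0769 against -0.0336 in the simulations, a difference of -0.0432.

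TNF-raised genes were also found among those lower with knockdown without TNF-a. The difference between this overlap and the one with TNF-a was not tested. With the block 5 of these 12 genes were TNF-raised (0.589 for independent lists, 12225 genes), namely Cxcl2, Il11, Csf3, Cyp1b1 and an unnamed locus. Cyp1b1 lost the call for TNF-a without set 1 (adjusted p = 0.0545) or 3 (0.110) and that for knockdown without set 2 (0.127). With all 12 libraries in the blocked fit it lost both (0.119 and 0.0666). Of the 2 higher with knockdown, 0 were (0.0982). These 5 were picked after their values were seen. The overlap with lower genes was 6 in edgeR with the block, 62 in DESeq2, 0 with all 12 libraries, and 30, 6 and 46 without set 1, 2 or 3. Without the block it was 0 in limma and 1 in DESeq2. The authors' deposited tables give 58 (15.3 for independent lists) and 7 higher (7.87). These comparisons share the PLKO_CTR libraries, for which simulated groups without any effect gave a correlation of fold changes of 0.50 (0.48 to 0.53), against -0.03 observed. The covariance was -0.00589 against 0.0338 in the simulations, a difference of -0.0397.

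Knockdown effects without and with TNF-a, which share no library, correlated across 12310 genes at r = 0.69 (rho 0.64, simulated 0.0027, -0.04 to 0.04, covariance 0.124). The simulated noise was independent between libraries. A difference between the shTon and PLKO cultures of a set that recurs with and without TNF-a would raise r and the shared counts too. Neither the simulated r nor the independent lists below account for it, and it was not tested. With the block 5 genes were lower in both, Cxcl2, Il11, Sacm1l, Ftl1 and Csf3, where independent lists would share 0.0169 of 12091 genes. Pappa was higher in both (0.00232 for independent lists), and 0 genes passed in opposite directions. The shared count of 6 was 7 in edgeR, 3 with all 12 libraries in the fit, 199 in DESeq2, 174 without set 1, 10 without set 2 and 23 without set 3. Without the block it was 0 in limma and edgeR and 5 in DESeq2. The authors' deposited tables share 123 lower genes (4.69 for independent lists) and 76 higher (2.10).

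**Figure D3:**
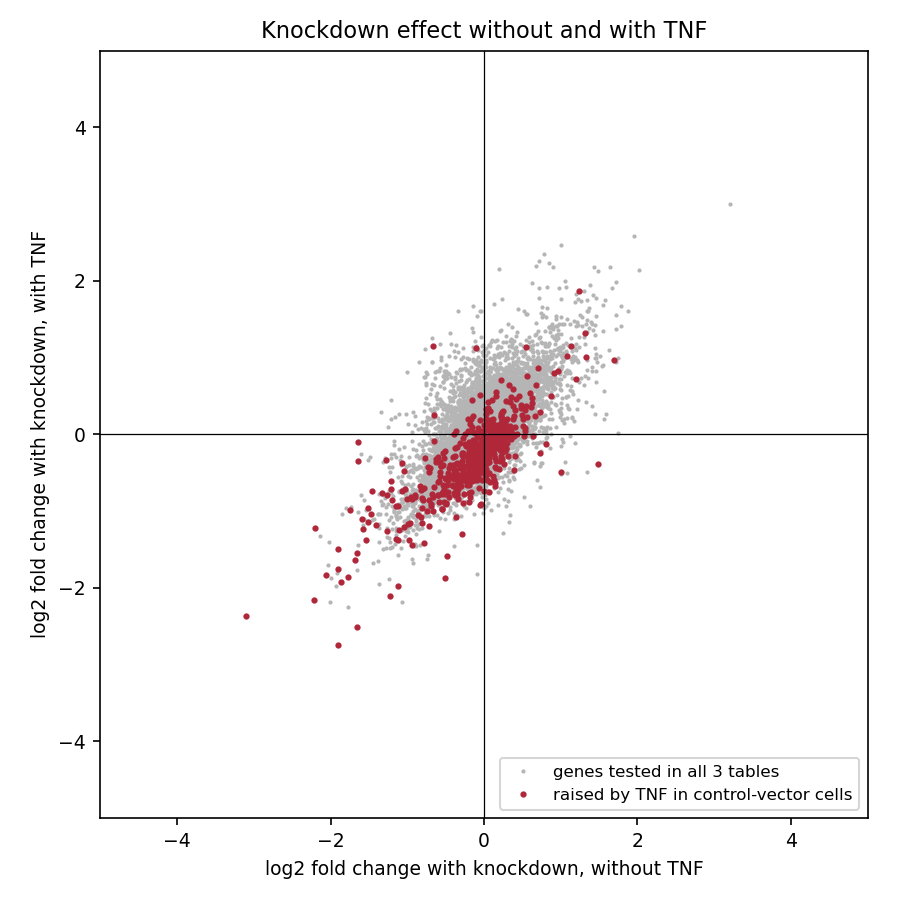
Log2 fold change of knockdown without TNF-a (x axis) against knockdown with TNF-a (y axis) for 12088 genes, with the 600 plotted genes that TNF-a raised in PLKO cells (adjusted p under 0.05, limma with the set as a block) in red. The points rise together along the diagonal (r = 0.69 over 12310 genes), and Cxcl2 and Il11 lie at the lower left.

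TNF-a in cells with the TonEBP shRNA (libraries labelled shTon_TNF against shTon_CTR) raised inflammatory and protease genes. Limma without the block passed 6 genes, all higher. They were Tnfaip3 (log2 fold change 2.72, SE 0.15, adjusted p = 0.00925), Plau, named after its values were seen (2.70, SE 0.17, adjusted p = 0.00925), and Tnfaip2, a TNF-inducible gene (2.63, SE 0.22, adjusted p = 0.0240). The apoptosis inhibitor gene Birc3 was higher as well (268 ± 20.9 to 1137 ± 131 normalised reads, SE 0.16, adjusted p = 0.0240). Mmp12 had 5.30 (SE 0.43, adjusted p = 0.0240) and Nos2 3.16 (SE 0.30, adjusted p = 0.0467). Without any 1 set that count was 0. Nos2 went from 22.3 ± 6.09 to 204 ± 28.9 normalised reads. With the block, Mmp9 rose from 52.2 ± 42.6 to 722 ± 474 (3.93, SE 0.23, adjusted p = 0.000691) and Cxcl2 from 323 ± 231 to 3774 ± 3049 (3.70, SE 0.40, adjusted p = 0.00641). Ibsp rose from 15.8 ± 18.4 to 585 ± 494 (5.47, SE 0.28, adjusted p = 0.000437). Hpgd, which degrades prostaglandins, fell from 375 ± 122 to 93.7 ± 39.7 (-2.05, SE 0.25, adjusted p = 0.00884). Blocked limma passed 405 of 12339 genes, 241 higher and 164 lower, against 1105 without set 1 and 143 without the mean-variance trend. Without the block edgeR passed 4, DESeq2 131 and limma over all 12 libraries 14, and with it DESeq2 passed 619.

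In these cells 14 of 20 TNF/NF-kB feedback genes rose and 0 fell (16 and 0 over the list alone, median 1.22, adjusted p = 1.86e-19). This list had adjusted p = 0.205 with an estimated correlation, and adjusted p = 0.00649 with one and no block. Of 15 chemokines 8 rose and 1 fell (10 and 1 over the list alone, median 2.10, adjusted p = 2.21e-10), and of 14 cytokines 8 rose and 0 fell (9 and 0, median 1.43, adjusted p = 4.54e-09). Of 13 mediator enzymes 7 rose and 0 fell (7 and 0, median 0.77, adjusted p = 1.98e-06). These 3 lists had adjusted p = 0.325 with an estimated correlation. Antigen presentation was higher (2 and 0 of 17, 6 and 0 over the list alone, median 0.30, adjusted p = 4.48e-05). Of 24 metalloproteinases and inhibitors 6 rose and 0 fell (7 and 2 over the list alone, median 0.04, adjusted p = 0.0248). Both had adjusted p = 0.609 with an estimated correlation. Skeletal muscle markers were lower in 9 of 10 (median -0.40, adjusted p = 0.00916, but 0.690 without the block, 0.0516 without set 2 and adjusted p = 0.488 with an estimated correlation). Mitochondrially encoded genes were higher in 8 of 9 (median 0.56, adjusted p = 0.00803, but 0.249 without set 1 and adjusted p = 0.609 with an estimated correlation). Osmoprotective targets did not pass (0 of 13, 2 and 1 over the list alone, median 0.05, adjusted p = 0.690).

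The interaction tests whether TNF-a acted differently in shTon and PLKO cells. It passed 0 of 12310 genes in limma without the block (29 at an unadjusted p under 0.05) and with it (219), and 0 in edgeR (57 and 259 of 12663) and DESeq2. In simulated data 18 of 100 genes with a 2-fold and 76 of 100 with a 4-fold interaction were recovered with the block, so most 2-fold differences were not detectable. The TNF-a effects on Il6, Cxcl2 and Il11, named after their values were seen, differed by -0.07 (SE 0.54), 0.05 (SE 0.79) and 0.23 (SE 0.48) on the log2 scale, with adjusted p = 0.999. Tnfaip2 had 0.60 (SE 0.25), Nos2 1.54 (SE 0.57) and the heme oxygenase gene Hmox1, also named after its value was seen, -1.37 (SE 0.41), each with adjusted p = 0.999. The signs for Il6, Cxcl2 and Il11 turn with other settings. Of the lists, bone and osteoclast markers passed without the block (adjusted p = 0.0387, and adjusted p = 0.268 with an estimated correlation). With the block these (median 0.46, adjusted p = 0.0267), cytokine and pattern-recognition receptors (0.21, 0.0267), antigen presentation (0.25, 0.0469) and fibrillar matrix genes (0.17, 0.0469) passed. Each of them had adjusted p = 0.691 with an estimated correlation, and 0 lists passed without set 2.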

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

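The tests of the 3 patterns weighed here were chosen only after the results were seen, and their intervals are 95% bootstrap intervals over genes, which are not independent replicates.

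4 named genes moved one way in all 3 sets under one condition and the other way in all 3 sets under the other. The differences were picked by direction and were not tested in that way, and the interaction test gave each an adjusted p of 0.999. Il15, a cytokine gene, had log2 ratios for knockdown of -0.27 ± 0.36 without and 0.31 ± 0.25 with TNF-a (mean ± SD of 3 sets), a difference of 0.58. Sacm1l had ratios for TNF-a of 0.19 ± 0.01 in PLKO and -0.07 ± 0.09 in shTon cells, a difference of -0.26. The bone transcription factor gene Runx2 had -0.63 ± 0.90 and 0.93 ± 0.89 (1.56), and Bgn, a matrix proteoglycan gene, -0.58 ± 0.64 and 0.70 ± 0.91 (1.28). Of 12310 genes, 141 (1.15%) moved in opposite ways in every set for knockdown and 189 (1.54%) for TNF-a, where signs drawn at random would give 3.125% each. Ratios of the same sign in every set were held by 2702 (21.9%) and 3232 (26.3%).

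The level of Nfat5 in the set 1 library labelled shTon_TNF goes against its label (log2 ratio 1.41 to the PLKO_TNF library of that set). The tables argue against a swap of these 2 libraries. The 264 genes lower with knockdown without TNF-a (the authors' deposited table) had a median log2 ratio of -0.50 (-0.54 to -0.45) between them, where a swap would put it above 0. A weaker knockdown response in that culture stays open, since this median is 53% (47.2 to 57.8) of the mean of sets 2 and 3 (-0.74 and -1.14), but set 1 also had the smallest median without TNF-a (-0.55, against -0.76 and -1.17). The 140 genes higher with knockdown without TNF-a had 0.73 (0.63 to 0.84) in set 1 with TNF-a, against 0.89 and 1.04. Without TNF-a they had 0.72, against 0.76 and 1.13. In both lists the medians of set 1 were thus much the same with and without TNF-a. Loss of the shRNA in part of the cells and a mixed library were not tested.

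Genes that TNF-a raised in PLKO cells were lower with knockdown under TNF-a, and both comparisons use the PLKO_TNF libraries. For genes raised in 2 sets and measured in the third, which shares no library with these, the knockdown log2 ratio with TNF-a had medians of -0.39 (719 genes, set 1), -0.29 (311, set 2) and -0.24 (469, set 3). The highest, -0.24 (-0.30 to -0.14), lies below 0, which argues against chance values of the shared libraries as the whole cause. Of 10000 lists matched on expression level 0% had a mean as low as -0.31 (their median -0.02), which argues against a trend with level or depth. A role of TonEBP in the response is one hypothesis and an off-target effect of the single shRNA another, neither of which was tested, and the interaction test passed 0 genes. Without TNF-a the same medians were -0.33 (-0.35 to -0.31), -0.10 (-0.18 to -0.01) and 0.00 (-0.06 to 0.07) in sets 1 to 3, with a mean of -0.14. Of the matched lists 0% had a mean as low there too (their median 0.00095). Lower values without TNF-a were thus seen in set 1 and weakly in set 2, but not in set 3, whose interval includes 0.

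With the set as a block and all 12 libraries in the fit, 444 genes passed for knockdown with TNF-a and 3 without it. For genes that passed with TNF-a in 2 sets (484, 155 and 32 genes), the log2 ratio in the remaining set, taken in the direction of the pick, averaged 0.75 (0.61 to 0.87) without TNF-a and 0.89 (0.78 to 1.01) with it. This argues against an effect of knockdown that is present with TNF-a alone. The ratio of the counts is no measure of a difference between the conditions, and a biological difference between them stays open, as untested beyond the interaction.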

How the results depend on the processing

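The count tests in edgeR, TMM scaling of the deposited values, the fits without a mean-variance trend, the combinations of the block with another setting and the fit without the set 1 library labelled shTon_TNF were chosen only after the data were seen. Unless a cause is named, the cause was not tested.

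With the set as a block the genes past the threshold went from 0 to 1190 for TNF-a in PLKO cells, from 0 to 14 for knockdown without TNF-a, from 0 to 31 for knockdown with TNF-a and from 6 to 405 for TNF-a in shTon cells. The interaction stayed at 0 in all settings run. Without the block, DESeq2 on recovered reads gave 146, 20, 41 and 131 for the first 4. With all 12 libraries it was 15 for TNF-a in PLKO and 14 in shTon cells, and 0 for both knockdown comparisons. For TNF-a in shTon cells an adjusted p under 0.01 gave 2, and each set left out gave 0, with fewer samples. The 3 other counts without the block stayed at 0 with a pseudocount of 0.1, no filter, no trend, TMM scaling, edgeR under its 4 settings, the 2 stricter thresholds and each set left out.

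With the block, the counts for TNF-a in PLKO cells, knockdown without, knockdown with TNF-a and TNF-a in shTon cells were as follows. A pseudocount of 0.1 gave 979, 2, 12 and 334, no filter 1263, 14, 31 and 410, and TMM scaling 1190, 14, 30 and 363. An adjusted p under 0.01 gave 149, 0, 0 and 109, a fold of at least 2 gave 407, 14, 31 and 267, and both are stricter by construction. No trend gave 55, 0, 0 and 143. On recovered reads edgeR gave 1215, 17, 21 and 391 and DESeq2 1356, 399, 367 and 619. All 12 libraries gave 696, 3, 444 and 333, and without the set 1 library labelled shTon_TNF the last 2 were 296 and 299. With 1 set left out the ranges were 545 to 1410 (968 without set 3), 12 to 283 (220 without set 3), 32 to 488 (157 without set 2) and 317 to 1105 (365 without set 2), the upper end being without set 1 in each.

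The overlap of TNF-raised genes with genes lower with knockdown under TNF-a (0 without the block) was 3 in DESeq2. With the block it was 11, 9 in edgeR, 89 in DESeq2, 42 with all 12 libraries and 12 to 79 with a set left out, and 82 in the authors' deposited tables. Genes shared by the knockdown comparisons (0 without the block) were 5 in DESeq2. With the block they were 6, 7 in edgeR, 199 in DESeq2, 3 with all 12 libraries and 10 to 174 with a set left out (23 without set 3), and 199 in the authors' deposited tables. An adjusted p under 0.01 left 0 in both.

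Lists past camera without the block numbered 5, 6, 10 and 9 in the same order of comparisons, and 1 for the interaction. An estimated correlation gave 0, 0, 0, 1 and 0, and 0 in all 5 with the block. The block gave 8 for TNF-a in PLKO cells and 4 for the interaction, and TMM scaling with the block 8 and 4. With a set left out as well, the lists were 6 to 13 for TNF-a in PLKO cells, 5 to 12 for knockdown without TNF-a and 0 to 7 for the interaction. For knockdown with TNF-a and TNF-a in shTon cells the counts with the preset correlation stayed within 1.5 times. Group means of Nfat5 under TMM scaling were 1347 in PLKO_CTR, 771 in PLKO_TNF, 417 in shTon_CTR and 835 in the libraries labelled shTon_TNF.

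Of the results for single named genes under other settings, 7373 kept direction and side of the threshold, 2090 passed it anew, 32 lost it and 92 changed sign, 58 of these in the interaction. These numbers start from the test without the block, which passed genes for TNF-a in shTon cells alone, so a loss was possible only there. Of the named genes past the threshold with the block (86, 10, 27 and 60), those still past it were 74, 10, 27 and 58 without set 1, 66, 4, 26 and 50 without set 2 and 70, 10, 18 and 50 without set 3, all with the same direction where a value was given. No trend left 15, 0, 0 and 33 and a pseudocount of 0.1 left 79, 2, 12 and 56. All 12 libraries left 67 (of 85 with a value), 2, 25 and 48, and without the set 1 library labelled shTon_TNF the last 2 were 18 and 45. EdgeR left 85, 10, 21 and 56 (of 58) and DESeq2 84, 10, 27 and 60. None of the sign changes concerned a gene that passed with the block in that comparison.

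Changes of sign with a set left out, where fewer samples stand behind each value, were the same with and without the block. The lowest and highest values for TNF-a in PLKO cells were -0.0938 (without set 3) and 0.361 for Slc6a6, which was also below 0 without set 1 (-0.0714). For knockdown without TNF-a they were -0.469 and 0.0032 (without set 1) for Akr1b1, and -0.986 and 1.10 (without set 3) for Adamts15. For knockdown with TNF-a they were -1.09 and 0.176 for Nfat5 (without set 2, and 0.145 without set 3), -0.683 and 0.311 for Nos2 (without set 2, and 0.0815 without set 3), and -0.593 and 0.207 (without set 3) for Slc6a6. For TNF-a in shTon cells they were -0.091 (without set 1) and 1.01 for Nfat5, -0.0386 (without set 1) and 0.544 for Slc6a6, -0.431 (without set 2) and 0.691 for Cd68, and -0.117 and 0.0235 (without set 2) for Timp2. In the interaction the sign changed without set 1 for Cxcl2 (-0.259 to 0.386), Il11 (-0.131 to 0.469) and Plau (-0.131 to 0.130). It changed without set 2 for Slc6a6 (-0.00976 to 0.637), and without set 3 for Cd68 (-0.843 to 0.322) and Cxcl1 (-0.0224 to 0.277). It changed without either of 2 sets for Ftl1 (-0.124 to 0.0403, and 0.00173 without set 1), Aldh1l2 (-0.401 to 0.177, and 0.176 without set 1) and Il6 (-0.496 to 0.282, and 0.0146 without set 3).

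Other changes of sign came with the count tests. Nfat5 for knockdown with TNF-a was 0.136 in DESeq2 and 0.155 in edgeR, 0.140 with RLE scaling, 0.153 with at least 1 read and 0.154 with 10 reads in 3 libraries. In the same order the interaction was -0.163, -0.161, -0.164, -0.164 and -0.163 for Cxcl2, -0.107, -0.132, -0.121, -0.133 and -0.134 for Mmp9, 0.104, 0.103, 0.105, 0.102 and 0.102 for Aldh1l2, and -0.0163, -0.0238, -0.0157, -0.0245 and -0.025 for Cyp1b1. With the block, edgeR and DESeq2 gave -0.119 and -0.0881 for Cxcl2, -0.166 and -0.139 for Mmp9 and 0.0235 and 0.0448 for Il6 in the interaction. Adamts15 for knockdown without TNF-a was 0.0306 in DESeq2 with the block. TMM scaling turned Plau in the interaction, with and without the block (-0.00118). Without the set 1 library labelled shTon_TNF, Nfat5 (-0.319) and Slc6a6 (-0.0772) turned for TNF-a in shTon cells. In the interaction Ftl1 (0.0107), Aldh1l2 (0.142), Il6 (0.202), Slc6a6 (-0.143), Mmp9 (-0.0393) and Cxcl12 (-0.120) did.

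With 7160042 reads in the shallowest and 18646798 in the deepest library, genes with a mean under 10 normalised reads were not tested, except in the settings without that filter. Changes of low genes are understated by the added 1. In simulated data with the block, 82 of 100 genes changed by a fold of 2 were recovered for TNF-a in PLKO cells and 18 of 100 for the interaction.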

Other observations

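The splits of the samples were planned, while the tests of differences among sets and of lists with the block and a set left out or an estimated correlation were chosen only after the data were seen. For TNF-a in PLKO cells, knockdown without and knockdown with TNF-a, the real count without the block is 0, so 10 of 10 splits of the 6 libraries reach it by construction (highest other 0, 2 and 0). For TNF-a in shTon cells 1 of 10 did (real 6, highest other 0). With the block, of the 4 splits that part every set, 1 gave as many genes as the real one in each comparison, namely itself (1190, 14, 31 and 405, highest other 0 in each). Splits of 6 libraries are too few for a share under 0.05. For the interaction the real count is 0 as well, so all 100 of 100 drawn splits reach it by construction, with and without the block, and nothing about chance follows. The highest other split gave 1266 genes without the block and 1880 with it, in splits within sets. A drawn split can set libraries given TNF-a against untreated ones, and its contrast then holds the effect of TNF-a. These high counts are therefore no chance level for the interaction. Which splits gave them was not examined.

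The sets differ in tissue markers. Skeletal muscle markers had median log2 deviations from the mean of the 12 libraries of 3.21, 1.46 and -4.46 in sets 1 to 3 (10 of 10 genes differing). Mylpf, a muscle myosin light chain gene, averaged 9603 ± 2848, 2996 ± 566 and 5.80 ± 4.41 normalised reads (SD, n = 4 libraries, 1 of each group). The embryonic myosin gene Myh3 had 27613 ± 12759, 9098 ± 3085 and 17.6 ± 17.3, and the muscle transcription factor gene Myod1 798 ± 356, 135 ± 79.1 and 5.62 ± 3.81. Outside muscle, the growth factor gene Igf2 had 4182 ± 1130.4, 1128 ± 176 and 0.317 ± 0.634. Dkk3, a Wnt antagonist gene, had 2497 ± 293 in set 1, 4878 ± 1066 in set 2 and 2.77 ± 1.01 in set 3, and Krt8 140.3 ± 72.0, 123 ± 51.3 and 1784 ± 507. These genes were picked after their values were seen. Krt8 is 1 of the nucleus pulposus and notochord markers, and that list went the other way. Its 10 genes had median deviations of 0.16, 0.51 and -0.70 in sets 1 to 3 (9 of 10 differing), lowest in set 3.

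Lists passed for TNF-a in shTon cells beyond those given with that comparison. With the block, cell cycle genes were lower (0 rose and 2 fell of 35, median -0.14, adjusted p = 0.0260, but 0.249 without set 1 and 0.0668 without set 2). Sterol synthesis genes were higher (1 and 0 of 21, median 0.18, adjusted p = 0.0154, but 0.0668 without set 2 and 0.339 without set 3). Annulus fibrosus and tendon markers were lower by value in 7 of 7 (median -0.50, adjusted p = 0.0174). With an estimated correlation these 3 had adjusted p of 0.609, 0.609 and 0.481. Macrophage and leukocyte markers (1 to 2 tested), endothelial markers (3 to 4) and erythroid markers (0) were too few to test.

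Hmox1, heme oxygenase, picked after its values were seen, rose with TNF-a in PLKO cells from 1980.5 ± 938 to 6009 ± 1543 normalised reads (log2 fold change 1.67, SE 0.26, adjusted p = 0.0171). In shTon cells it went from 1159 ± 327 to 1560.2 ± 959 (0.29, SE 0.18, adjusted p = 0.434). The interaction did not pass (-1.37, SE 0.41, adjusted p = 0.999), so a difference between the cells is not shown.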
